A study of Mus musculus with 6 samples.

How the data were processed

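Total RNA of 6 snap-frozen Renca tumors was measured on Affymetrix Mouse Gene 1.0 ST arrays with biotin-labelled cRNA, 3 tumors grown in the kidney and 3 grown under the skin, each in a separate BALB/c mouse and taken 12 days after injection, per the labels. The deposited values were log2 expression values made by the authors with RMA and the affy package, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of a transcript cluster, which compresses changes of dim features. The versions, settings and probe set definition behind these values and the genome build were not given in the sources used here, and the log2 scale was taken from the values, which ran from 2.31 to 15.07. Whether all 6 arrays were normalized together stays unknown. The median of all values per array was 7.08, 7.11 and 7.08 for intrakidney tumors 1, 2 and 3 and 7.09, 7.10 and 7.11 for subcutaneous tumors 1, 2 and 3. The number of arrays limits the precision.

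The value table held 35512 transcript clusters. The platform annotation paired 21789 of them with exactly 1 gene, 1621 with several genes, and 12102 were not named here. Of the clusters with 1 gene, 21698 were matched by Entrez identifier to a gene-name reference of the assembly GRCm38.p6, used only for names, and 0 symbols were updated. Only clusters with exactly 1 gene entered the gene-level test, and for 999 genes with more than 1 cluster the cluster with the highest mean over all 6 arrays was taken, which left 19938 genes. The 13723 clusters paired with several genes or not named held 0 past the threshold when every cluster was tested with limma. No cluster of any kind passed in that test, so it cannot show that these clusters hold no difference. No filter on dim genes was set. No genomic positions are given.

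Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, eBayes with a constant prior, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All log2 fold changes are intrakidney minus subcutaneous, and standard errors are those of the moderated fit. The labels named no batch. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 37 lists, or over the 5 further lists for those chosen after values had been seen, and every adjusted p of a list is from camera unless another test is named. Of 525 list memberships 486 were measured, and at least 3 measured members were needed. Members that had no cluster of their own, among them C3, Spp1, Cfd, Lck, H2-K1 and Gapdh, were not analysed here. List means per array were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. The groups, the tests, the gene lists, the other settings to be tried and the rule for naming genes were set before the data were examined.

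The rule named the 10 genes with the largest increases and the 10 with the largest decreases among those past the threshold whose groups do not overlap, leaving out names that are only an accession or a provisional identifier. It also named up to 4 members of each list in order of adjusted p, and 9 genes whatever their values: Ccl2, Il10, Arg1, Mrc1, Ifng, Cd274, Foxp3, Tgfb1 and Vegfa. A gene named outside this rule is said to have been chosen after its values were seen, except where a range of values is given by its end members or a count is spelled out.

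The other settings set in advance were quantile normalization, median centring, leaving out genes under the 40th percentile of mean value, an offset of 16 on the linear scale, testing every cluster, averaging the clusters of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array in turn, a stricter adjusted p of 0.01, camera with an estimated correlation, and the rotation test fry. The median log2 fold change of all genes was -0.0058 as deposited, -0.0073 after quantile normalization and -0.0094 after median centring.

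The fit was tested on simulated data with 10 simulations of the comparison over 19938 genes, each with 200 changed genes. It recovered 62.4% of genes changed by 0.5 on the log2 scale, 97.9% of those changed by 1 and 100% of those changed by 2, and 3.97% of all calls were false. A list of 20 genes shifted by 0.3 was recovered in 10 of 10 simulations, and 0 of 360 unshifted lists passed with camera. The simulated noise was independent between genes, unlike that of the arrays, where other splits of the 6 arrays gave 5 to 13 lists with camera's preset correlation. It also had the same spread in both groups, unlike genes such as Arg1 (SD 0.779 in intrakidney and 0.055 in subcutaneous tumors). Arg1 differed by 2.007 on the log2 scale and did not pass. The simulated spread was that of the moderated fit, and 200 genes were changed where the arrays gave 46 past the threshold. On the arrays 18 genes passed with a change of at least 2-fold. Adipoq, Cd163 and Il33 differed by 1.144, 1.043 and 1.414 and did not pass (limma, adjusted p = 0.0587, 0.0744 and 0.110). The shares recovered therefore may not hold for these arrays. Figures were drawn with matplotlib 3.10.9 and tables were joined with pandas 2.3.3 in Python 3.11.15.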

Results

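The series compared tumors of Renca, a renal carcinoma cell line that arose in a BALB/c mouse, grown at 2 sites in BALB/c mice. Cells had been injected under the skin or into the outer layer of the kidney, and the tumors were excised on day 12. RNA of 3 intrakidney tumors and 3 subcutaneous tumors, each from its own mouse, was hybridised to whole-transcript mouse gene arrays. The values were log2 RMA intensities, with a median between 7.08 and 7.11 on each of the 6 arrays, and 19938 genes were tested. Pearson correlations across these genes, which are not independent replicates, lay between 0.995 and 0.997 within the subcutaneous group, between 0.991 and 0.994 within the intrakidney group, and between 0.990 and 0.996 across groups. The leading principal component did not separate the groups. The number of arrays limits the precision of every value given here.

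The comparison asked how the site of growth was reflected in the RNA of tumors grown from the same cells. The largest increase in intrakidney tumors among genes past the threshold was that of Car3 (transcript cluster 10490913), a carbonic anhydrase abundant in fat and slow muscle, which rose 10.6-fold from a log2 value of 6.66 ± 0.41 to 10.06 ± 0.31 (SD, n = 3 per group). Fabp4, a fatty acid carrier of adipocytes, macrophages and capillary endothelium, rose 4.23-fold, and Alox15, a lipoxygenase of eosinophils and resident peritoneal macrophages, rose 3.25-fold. The largest decreases were those of Anxa8, an annexin of epithelial cells, which fell by 2.16 on the log2 scale (4.47-fold), and of the matrix glycoprotein genes Tnn, Thbs2 and Postn, which fell by 1.84, 1.75 and 1.66.

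With limma, 46 of the 19938 genes passed an adjusted p of 0.05, of which 26 were higher and 20 lower in intrakidney tumors, and 18 of the 46 changed at least 2-fold. At an unadjusted p of 0.05, 1681 genes passed, 941 of them higher and 740 lower. All 46 genes had intrakidney arrays that did not overlap with the subcutaneous arrays, a state that 14.9% of all genes showed and that chance gives in 10% for 3 against 3. The count depended on single arrays: it was 2 without subcutaneous tumor 1, 3 without subcutaneous tumor 2, 4 without subcutaneous tumor 3 and 21 without intrakidney tumor 1. The genes higher in intrakidney tumors numbered 16 without intrakidney tumor 3, and the genes lower numbered 12 without intrakidney tumor 2. Other settings gave larger counts: 624 with array weights, 138 with an intensity trend and robust prior, and 101 without dim genes. The array weights rested the intrakidney group mostly on intrakidney tumor 3 (2.571, against 0.351 and 0.679). They rested the subcutaneous group mostly on subcutaneous tumor 2 (3.549, against 0.756 and 0.609). Intrakidney tumor 3 also had the highest mean over the proximal tubule list (7.37). The replicate number as a block gave 0. With the proximal tubule level as a covariate, chosen after the values were seen, 9 passed. The count was 0 when every row of the array was tested, with a smallest adjusted p of 0.0574 and 2206 rows at an unadjusted p of 0.05. The sign of all 46 genes and an unadjusted p under 0.05 were kept in that setting and without each array. These genes were called on the same arrays and their groups do not overlap, which largely fixes that outcome, so it does not measure robustness.

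**Figure D1:**
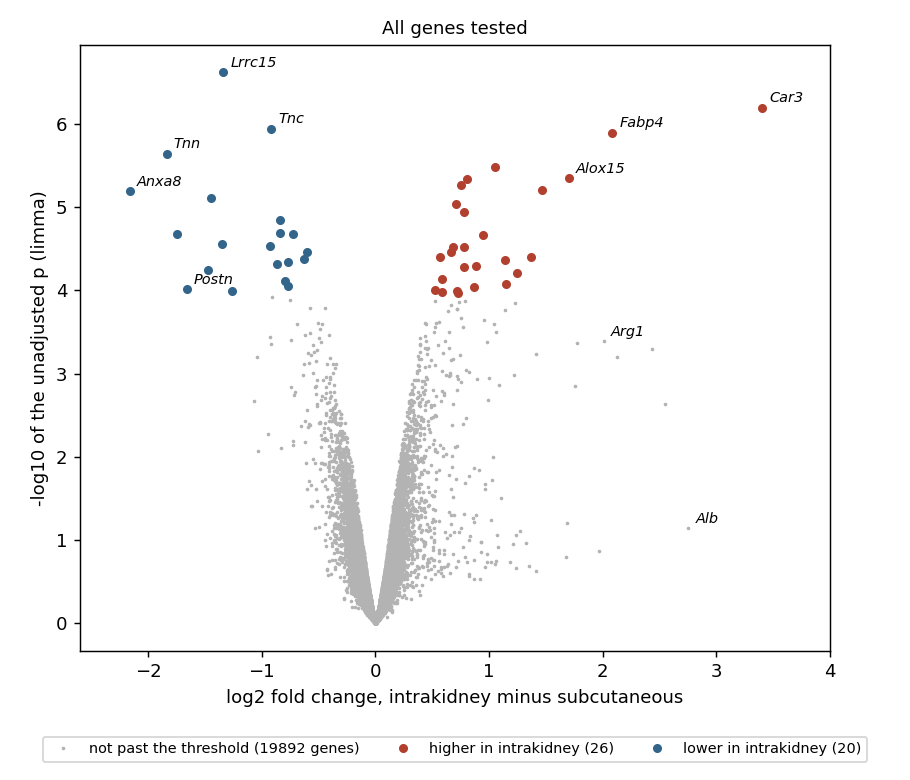
Each point is 1 of the 19938 genes tested, placed by its log2 fold change (intrakidney minus subcutaneous, 3 arrays per group) and the negative log10 of its unadjusted p from limma. The 26 genes that rose are red, the 20 genes that fell are blue, and Arg1 and Alb, the latter labelled after its values were seen, lie among the genes in grey that did not pass the adjusted threshold.

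Of the other genes among the 10 largest increases, Mgp, an inhibitor of calcification in vessels and cartilage, rose by 1.46 ± 0.13 on the log2 scale (SE, adjusted p = 0.0117). Vsig4, a complement receptor of tissue-resident macrophages, rose by 1.37 ± 0.16, and the chemokine gene Ccl6 rose by 1.24 ± 0.16. Timp3, an inhibitor of matrix metalloproteinases, rose by 1.15, and F13a1, the clotting factor XIII subunit made by macrophages, rose by 1.14. Hsd11b1, which regenerates active glucocorticoid, rose by 1.05 ± 0.09, and Lrg1, a secreted glycoprotein of the acute phase, rose by 0.95 ± 0.10. The remaining 16 of the 26 genes rose by 0.53 (Ccl24) to 0.89 (Esm1, a proteoglycan gene of sprouting endothelium).

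Among the largest decreases, Lrrc15 (transcript cluster 10438904), a membrane protein gene of activated fibroblasts, had the lowest adjusted p of all genes (0.00475), with a log2 value of 6.59 ± 0.07 in intrakidney and 7.93 ± 0.09 in subcutaneous tumors (SD, n = 3 per group). Aspn, a small leucine-rich proteoglycan of connective tissue, fell by 1.47 on the log2 scale, C1qtnf3, a secreted protein related to complement C1q, fell by 1.45, and the protease-like gene Prss35 fell by 1.35. Akr1c18, which inactivates progesterone, fell by 1.26 and Crabp1, a retinoic acid-binding protein gene, fell by 0.93. The remaining 10 of the 20 genes fell by 0.60 (Col6a2) to 0.92 (Tnc) on the log2 scale.

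**Figure D2:**
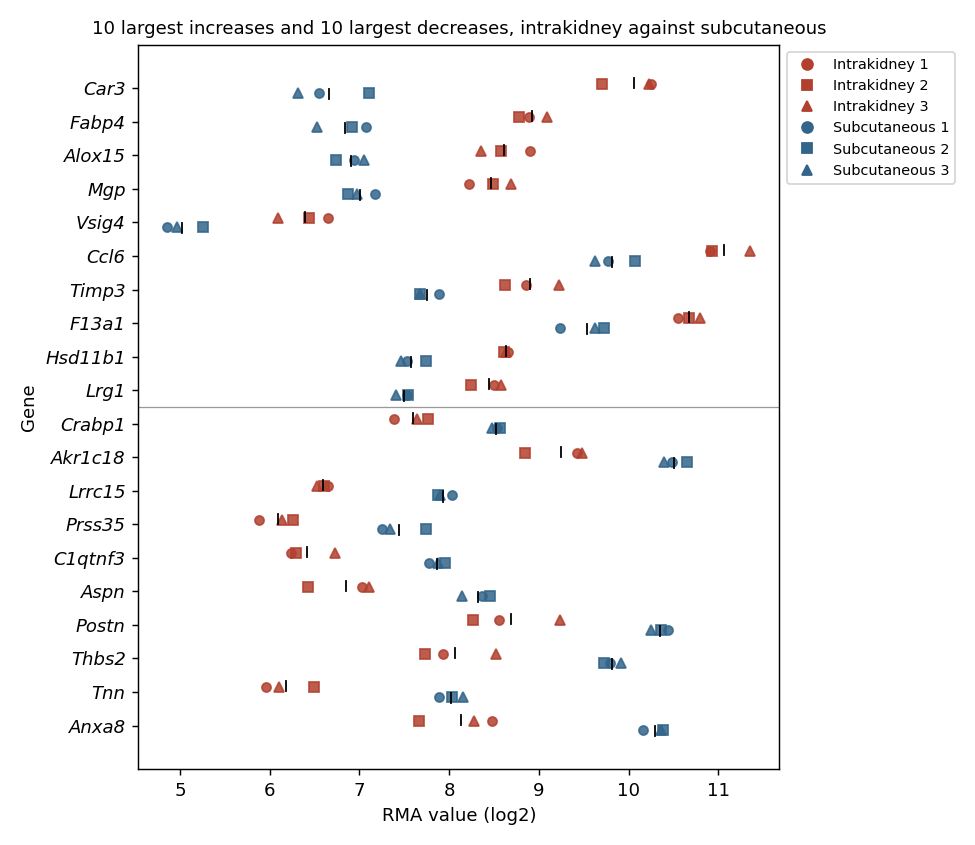
Log2 RMA value (horizontal axis) of the 10 genes with the largest increases and the 10 with the largest decreases among those past the threshold, with 1 point per array and a black tick at each group's mean. Car3 lies between 9.71 and 10.24 in intrakidney and between 6.31 and 7.11 in subcutaneous tumors, and no gene shown has overlapping groups.

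Of 37 gene lists fixed before the data were examined, 11 passed with camera's preset correlation, 8 of them higher and 3 lower in intrakidney tumors. That count was reached by 4 of the 10 splits of the 6 arrays into 3 and 3, the real split included. The number of lists therefore does not set the real groups apart. With an estimated correlation 0 lists passed, and with the rotation test fry, which does not compare a list with other genes, 3 passed: alternatively activated macrophage, chemokine and adipocyte genes. By exact permutation of list means, 10 lists had the groups farther apart than any other split (two-sided exact permutation p = 0.1 each, 0.37 after adjustment over the 37 lists), among them the 3 lists that passed with fry.

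Genes of fibroblasts and of the extracellular matrix were lower in intrakidney tumors as a group. Of 19 measured members, 16 lay lower, and 4 fell past the threshold over all genes: Postn, the adhesion glycoprotein Tnc by 0.92, and the collagen VI chains Col6a1 by 0.84 and Col6a3 by 0.73 on the log2 scale. Adjusted over the list alone, 11 members were lower and 1, Fn1, was higher. The median log2 fold change was -0.55 (camera, adjusted p = 7.949e-12), while adjusted p = 0.285 with an estimated correlation. The mean over the list was 9.40 ± 0.27 in intrakidney and 9.87 ± 0.06 in subcutaneous tumors (SD, n = 3 per group), which were farther apart than in any other split of the arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

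Genes of alternatively activated macrophages, a state tied to tissue repair, were higher in intrakidney tumors as a group, with 14 of 18 members higher and a median log2 fold change of 0.29 (camera, adjusted p = 3.125e-09; adjusted p = 0.0850 with an estimated correlation). Of the members, 2 rose past the threshold over all genes, the chemokine gene Ccl24 by 0.53 ± 0.07 and the folate receptor gene Folr2 by 0.58 ± 0.08 on the log2 scale (SE). Adjusted over the list alone, 11 members were higher and 0 lower. Arg1, which breaks down arginine, measured 10.32, 8.99 and 10.36 in the intrakidney tumors and 7.82 to 7.92 in the subcutaneous tumors, a 4.02-fold difference that missed the threshold over all genes (adjusted p = 0.0947). The scavenger receptor gene Cd163 differed by 1.04 (adjusted p = 0.0744) and the mannose receptor gene Mrc1 by 0.39 (adjusted p = 0.212). Il10 and Tgfb1, which encode immunosuppressive cytokines, differed by -0.09 and -0.003. The list of general macrophage genes had a median log2 fold change of 0.08 over 13 members (adjusted p = 0.189), which was 0.13 (adjusted p = 0.00581) without intrakidney tumor 3 and 0.22 (adjusted p = 4.732e-05) without intrakidney tumors 2 and 3, and its member nearest to the threshold, the lipopolysaccharide co-receptor gene Cd14, differed by 0.44 (adjusted p = 0.0744) and was the only 1 higher when adjusted over the list alone. Genes of classically activated macrophages had a median of 0.11 (adjusted p = 0.123), or 0.16 (adjusted p = 0.00455) without intrakidney tumor 2, with Tnf at 0.39 and Nos2 at -0.38.

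Chemokine and chemokine receptor genes were higher as a group, with 15 of 22 members higher and a median log2 fold change of 0.27 (camera, adjusted p = 2.05e-06; adjusted p = 0.0866 with an estimated correlation). Ccl6 was the only member past the threshold over all genes, and 10 members were higher and 0 lower when adjusted over the list alone. The monocyte-attracting chemokine genes Ccl2, Ccl7 and Ccl12 differed by 0.72 ± 0.14, 0.75 ± 0.13 and 0.90 ± 0.18 (SE), with adjusted p = 0.149, 0.110 and 0.152. The median of the list was 0.13 without intrakidney tumor 3 (adjusted p = 3.05e-06).

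Genes of T cells were lower in intrakidney tumors as a group: all 14 measured members lay lower, with a median log2 fold change of -0.21 (camera, adjusted p = 5.191e-06; adjusted p = 0.285 with an estimated correlation). None passed over all genes, and 5 were lower when adjusted over the list alone. The genes Cd3d and Cd3e, whose proteins associate with the T cell receptor, differed by -0.49 and -0.41. Cd4 differed by -0.42 and the co-stimulatory receptor gene Icos by -0.34. Intrakidney tumors 2 and 3 held more transcripts of kidney tubule, and without these arrays the T cell median was -0.18 (adjusted p = 0.119). Without intrakidney tumor 3 alone it was -0.14 (adjusted p = 0.00117). Genes of cytotoxic T and NK cells had a median of -0.06 (adjusted p = 0.188), or -0.12 (adjusted p = 0.00960) without intrakidney tumor 1, with Il2rb at -0.47 and Ifng at -0.06. Genes of type 2 and regulatory T cells had a median of -0.07 and a mean of 0.02, which differ in sign (adjusted p = 0.188), with Foxp3, the regulatory T cell factor, at -0.18 and the alarmin gene Il33 at 1.41 (adjusted p = 0.110), the only member of these lists that was higher when adjusted over the list alone. Immune checkpoint genes had a median of -0.07 (adjusted p = 0.0665), or -0.11 (adjusted p = 0.000375) without intrakidney tumor 1, with Havcr2 at -0.47, Ctla4 at -0.34 and Cd274, which encodes PD-L1, at -0.05.

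Endothelial genes were higher as a group, with 13 of 16 members higher and a median log2 fold change of 0.17 (camera, adjusted p = 2.05e-06; adjusted p = 0.285 with an estimated correlation). Emcn, which encodes a sialomucin of capillaries and veins, rose by 0.72 ± 0.10 on the log2 scale (SE, adjusted p = 0.0460) and was the only member past the threshold over all genes. Adjusted over the list alone, 5 members were higher and 0 lower. The vessel receptor genes Tek and Flt1 differed by 0.40 and 0.43. The array means of the list were 8.23 ± 0.008 and 8.03 ± 0.08 (SD, n = 3 per group, two-sided exact permutation p = 0.1). Angiogenic factor genes had a median of -0.03 (adjusted p = 0.996), with 3 members higher and 1 lower when adjusted over the list alone and 0 past the threshold over all genes. Vegfa, the main growth factor of endothelium, differed by -0.004, and Vegfd by -0.59 (adjusted p = 0.109).

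Adipocyte genes were higher as a group, with 9 of 10 members higher, a median log2 fold change of 0.15 and a mean of 0.60 (camera, adjusted p = 8.761e-06; adjusted p = 0.171 with an estimated correlation). Car3 and Cidec, a lipid droplet protein gene, rose past the threshold, Cidec by 0.66 ± 0.08 on the log2 scale (SE), and 4 members were higher when adjusted over the list alone. The adipokine genes Adipoq and Retn differed by 1.14 (adjusted p = 0.0587) and 0.57 (adjusted p = 0.204). The median was 0.09 without intrakidney tumor 3 (adjusted p = 5.12e-05) and 0.09 without subcutaneous tumor 1 (adjusted p = 6.12e-05).

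Transcripts of kidney tubule differed between the intrakidney arrays. The mean over 22 proximal tubule genes was 6.46, 6.85 and 7.37 in intrakidney tumors 1, 2 and 3 and 6.41 to 6.54 in the subcutaneous tumors (two-sided exact permutation p = 0.3). The list's median log2 fold change was 0.24 (camera, adjusted p = 0.000343; adjusted p = 0.621 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. It was 0.44 without intrakidney tumor 1 and 0.13 without intrakidney tumor 3 (adjusted p = 1.647e-09 and 0.0407). Without intrakidney tumors 2 and 3 it was -0.12 (adjusted p = 0.599). Cyp2e1, a cytochrome of tubule and liver, differed by 2.55 and the gluconeogenic gene Pck1 by 0.64 (adjusted p = 0.209 and 0.436). Genes of the loop, distal tubule and collecting duct had a median of 0.06 (adjusted p = 0.245), or 0.14 without intrakidney tumor 1 (adjusted p = 0.000375), and passed in the opposite direction without intrakidney tumors 2 and 3 (-0.15, adjusted p = 0.0269), with Umod at 1.07. Glomerular genes had a median of -0.02 (adjusted p = 0.545), with Clic5 at -0.31, the only member of either list that was lower when adjusted over the list alone. Without intrakidney tumors 2 and 3, a setting chosen after the values were seen, 30 genes passed over all genes, 17 higher and 13 lower, of which 13 were among the 46.

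**Figure D3:**
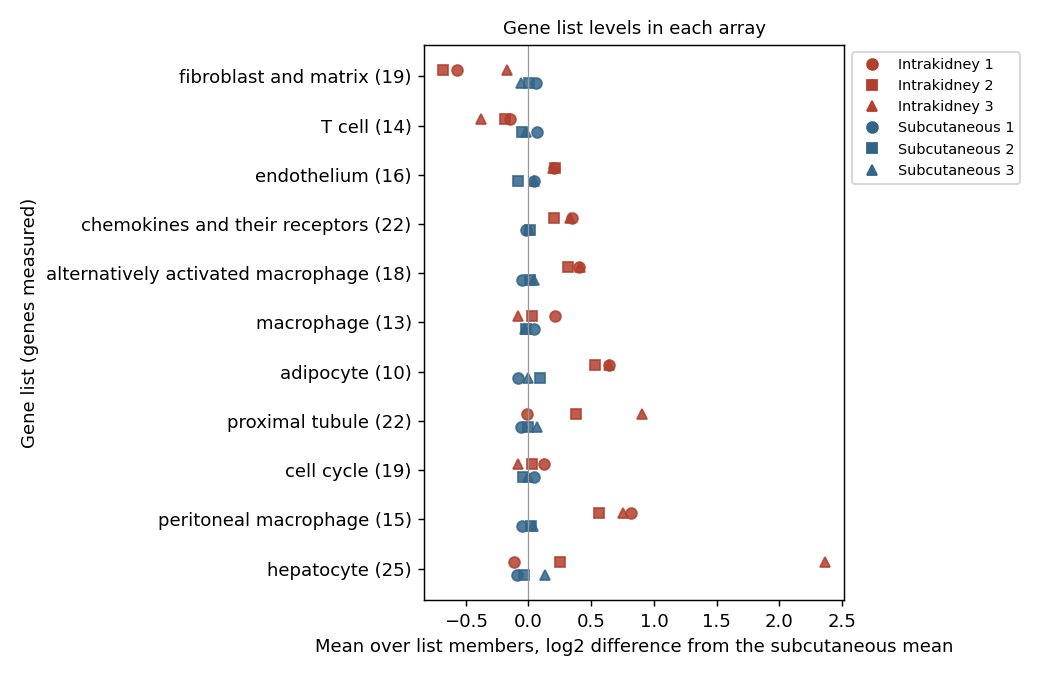
Mean over the measured genes of 11 gene lists on each array, as the log2 difference from the mean of the 3 subcutaneous arrays (horizontal axis), with 1 point per array and the number of genes in brackets. The fibroblast and matrix list lies at -0.57, -0.68 and -0.17 in the intrakidney tumors and the hepatocyte list at -0.12, 0.25 and 2.37; the peritoneal macrophage and hepatocyte lists were written after the values had been seen.

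Further lists passed with camera's preset correlation by a small margin. Neutrophil genes had a median log2 fold change of 0.20 (adjusted p = 0.0114; adjusted p = 0.588 with an estimated correlation), and adjusted p = 0.0697 without subcutaneous tumor 1, with S100a8 at 0.77 and Cxcr2 at 0.83. They also passed no longer without intrakidney tumors 2 and 3 (median 0.10, adjusted p = 0.306) or without dim genes (0.40, adjusted p = 0.193). Complement genes had a median of 0.16 (adjusted p = 0.0355; adjusted p = 0.709 with an estimated correlation), and C5ar1, the receptor of the anaphylatoxin C5a, rose by 0.81 ± 0.07 on the log2 scale (SE, adjusted p = 0.0113). The complement median was 0.06, 0.13 and 0.12 without intrakidney tumor 1, intrakidney tumor 3 or subcutaneous tumor 3 (adjusted p = 0.446, 0.228 and 0.457), 0.34 without intrakidney tumor 2 (adjusted p = 6.355e-05) and 0.47 without intrakidney tumors 2 and 3 (adjusted p = 0.00115). Red blood cell genes, of which 3 were measured, had a median of 0.22 (adjusted p = 0.0355; adjusted p = 0.312 with an estimated correlation), which was 0.15 without intrakidney tumor 3 and 0.21 without subcutaneous tumor 1 (adjusted p = 0.0734 and 0.0978), and 0.125 without intrakidney tumors 2 and 3 (adjusted p = 0.165). Skeletal muscle genes had a median of -0.08 (adjusted p = 0.0480; adjusted p = 0.827 with an estimated correlation). That median was -0.01, -0.06 and -0.04 without intrakidney tumor 1, intrakidney tumor 3 or subcutaneous tumor 3 (adjusted p = 0.517, 0.0647 and 0.457), -0.17 and -0.15 without intrakidney tumor 2 or subcutaneous tumor 1, and -0.23 without intrakidney tumors 2 and 3 (adjusted p = 0.00208). Skeletal muscle genes passed no longer with an offset or with every row of the array (adjusted p = 0.0521 and 0.0633), red blood cell genes after quantile normalization (adjusted p = 0.0795), and complement and skeletal muscle genes with array weights (adjusted p = 0.0735 and 0.184) or without dim genes (adjusted p = 0.114 and 0.193). Adjusted over each list alone, 2 complement genes and 1 red blood cell gene were higher, against 0 neutrophil and 0 skeletal muscle genes.

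The remaining lists did not pass. Of the tumor cell programmes, cell cycle genes had a median log2 fold change of 0.007 (adjusted p = 0.401), epithelial and mesenchymal state genes 0.01 with a mean of -0.02 (adjusted p = 0.906), and renal carcinoma epithelium genes 0.08 with a mean of 0.22 (adjusted p = 0.0691). The array means of the renal carcinoma list were farther apart than in any other split (0.22 against at most 0.19, two-sided exact permutation p = 0.1). So were those of the oxidative phosphorylation list (0.056 against at most 0.05, two-sided exact permutation p = 0.1). Cdh1, which encodes E-cadherin, differed by -0.52, Cdh2 by 0.41 and the iron-binding lipocalin gene Lcn2 by 1.22 (adjusted p = 0.147). Hypoxia and glycolysis genes had a median of -0.07 (adjusted p = 0.123), which was -0.14 (adjusted p = 1.29e-05) without intrakidney tumor 3 and -0.20 (adjusted p = 0.00451) without intrakidney tumors 2 and 3, with Bnip3 at -0.44. They also passed without dim genes (-0.08, adjusted p = 0.0261). Oxidative phosphorylation genes had a median of 0.05 (adjusted p = 0.144), fatty acid oxidation genes 0.02 (adjusted p = 0.906), and immediate early and heat shock genes 0.02 (adjusted p = 0.545). Cell cycle genes had a median of 0.06 without intrakidney tumor 3 (adjusted p = 0.0268) and 0.11 without intrakidney tumors 2 and 3 (adjusted p = 0.00189). The renal carcinoma list passed without intrakidney tumor 1, intrakidney tumor 3 or subcutaneous tumor 2 (adjusted p = 0.0231, 0.0472 and 0.0415), and after quantile normalization or median centring (adjusted p = 0.0430 and 0.0485). Adjusted over each list alone, Lcn2 and the immediate early genes Ier2 and Junb (0.38 and 0.28) were higher and Cdh1 was lower, and none of them passed over all genes.

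Interferon response genes had a median of 0.03 (adjusted p = 0.543), or 0.16 (adjusted p = 0.00544) without intrakidney tumor 2. Antigen presentation genes of MHC class I and class II had medians of -0.04 and -0.16 (adjusted p = 0.552 and 0.401), or -0.12 and -0.29 (adjusted p = 0.0161 and 0.0134) without intrakidney tumor 1. Without intrakidney tumors 2 and 3, which held more tubule transcripts, these medians were 0.13 and 0.07, with intrakidney tumor 1 alone left. The class I list lay at 0.138 in intrakidney tumor 1 and 0.117 in subcutaneous tumor 1, relative to the subcutaneous mean. The class II list lay at 0.155 and 0.073. With an estimated correlation over all arrays, the interferon, class I and class II lists had adjusted p = 0.904 each (camera). Dendritic cell genes had a median of 0.01 and a mean of -0.02 (adjusted p = 0.561), with the migration receptor gene Ccr7 at -0.45 (adjusted p = 0.0587). Genes of B cells and of mast cells and eosinophils had medians of -0.003 and -0.006 and means of 0.01 and 0.05, again of opposite sign (adjusted p = 0.812 and 0.756). Smooth muscle and pericyte genes had a median of 0.05 (adjusted p = 0.108), Schwann cell genes -0.09 (adjusted p = 0.310) and keratinocyte genes -0.04 (adjusted p = 0.545), with the cornified envelope gene Sprr1a at -0.48. Reference genes had a median of -0.007 (adjusted p = 0.543). Of the sex-linked genes (median 0.005, adjusted p = 0.756), Xist measured 9.46 ± 0.18 and 9.53 ± 0.15 (SD, n = 3 per group), and the Y-linked genes Uty, Kdm5d and Eif2s3y had group means between 3.32 and 4.57. None of the members of these lists passed over all genes. Adjusted over the list alone, Ccr7 was lower, the contractile genes Acta2 and Tagln of smooth muscle (0.37 and 0.39) were higher, and 0 members of the interferon, antigen presentation, B cell, mast cell and eosinophil, Schwann cell, keratinocyte, reference and sex-linked lists passed.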

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

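The covariate of proximal tubule level, the setting without intrakidney tumors 2 and 3, and 5 further gene lists were chosen after seeing the data. All 46 genes kept their sign and an unadjusted p under 0.05 in every setting that tested them (43 of the 46 were tested without dim genes). As the same arrays called them, this was largely fixed in most settings and does not measure robustness. The number past the adjusted threshold moved, and the cause was not tested unless stated. Quantile normalization gave 57 genes, 43 of them among the 46, median centring gave 62 with all 46 among them, and the mean of a gene's clusters gave 46.

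Genes past the threshold numbered 101 without dim genes, where fewer genes are tested (63 higher, 38 lower), 74 with the offset (45 higher), 138 with the trend and robust prior (94 higher, 44 lower), and 624 with array weights (373 higher, 251 lower, 49 at least 2-fold). The array weights ran from 0.351 to 3.549. With every cluster tested, limma gave 0 genes, 0 higher, 0 lower and 0 at least 2-fold, with 2206 clusters at an unadjusted p under 0.05 and a smallest adjusted p of 0.0574. The stricter adjusted p left 5 genes (2 higher, 3 lower, 4 at least 2-fold). With the tubule covariate, which costs a degree of freedom, 9 genes passed (4 higher, 5 lower, 8 at least 2-fold), all of them among the 46. Without intrakidney tumors 2 and 3, 30 passed (17 higher, 13 lower, 28 at least 2-fold). There the lone intrakidney tumor is assumed to vary like the subcutaneous tumors.

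Leaving out each array in turn gave 2 to 33 genes, 1 to 19 higher, 1 to 17 lower, 2 to 22 at least 2-fold, and 9 to 15 lists. Of the 2827 values of the 169 named genes under all settings, 2552 kept their side of the threshold, 73 came to pass and 202 no longer passed. Of these, 50 values, of 22 genes, had the opposite sign, and 0 of the 50 passed there or as reported. Of 700 list medians 64, of 21 lists, had the opposite sign, of which 8 passed there or as reported.

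With the replicate number as a block, limma gave 0 genes past the threshold, 0 higher, 0 lower and 0 at least 2-fold, with 1825 genes at an unadjusted p under 0.05, a smallest adjusted p of 0.0577, and 11 lists. The red blood cell list no longer passed (adjusted p = 0.0568) and the immune checkpoint list did (adjusted p = 0.0497). Deviations from the group means correlated across genes at 0.374, -0.159 and 0.104 for equal numbers, and at 0.429 for intrakidney tumor 2 with subcutaneous tumor 3. So samples were not taken as pairs, and whether numbers mark a shared day or batch stays unknown.

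Of the lists, 7 passed without dim genes, 0 with an estimated correlation and 3 with fry. Without dim genes the proximal tubule (adjusted p = 0.0809), neutrophil, complement and skeletal muscle lists no longer passed, and red blood cell genes were too few to test. With array weights 15 lists passed, but not complement and skeletal muscle. MHC class II (median -0.36), classically activated macrophage (0.238), loop, distal tubule and collecting duct (0.169), interferon (0.14), cytotoxic (-0.073) and checkpoint (-0.096) lists came to pass. The proximal tubule list changed direction with the tubule covariate (-0.032) and without intrakidney tumors 2 and 3 (-0.12), as it is built from these levels. So did the loop, distal tubule and collecting duct list (-0.096 and -0.15). MHC class I presentation (0.095 and 0.129) and class II presentation (0.153 and 0.072) changed direction too. All of these but the proximal tubule list passed with the covariate. Without intrakidney tumors 2 and 3, the spread between intrakidney tumors could not be measured. The T cell (-0.144 and -0.176, against -0.21), neutrophil (0.088 and 0.095, against 0.196) and red blood cell lists (0.107 and 0.125, against 0.222) no longer passed in either setting (adjusted p = 0.0656 to 0.417 with the covariate). Complement and skeletal muscle medians were 0.26 and -0.126 with the covariate. Hypoxia and glycolysis (-0.202 and -0.201), macrophage (0.155 and 0.220) and cell cycle (0.090 and 0.110) lists came to pass in both settings, and oxidative phosphorylation (0.063) with the covariate only. No other list fixed in advance shared measured members with a kidney segment list, so the alternative without such members was not run. Signal over background, which limits dim genes most, is not given by the values used here.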

Other observations

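The lists of hepatocyte, acute phase, peritoneal macrophage, mesothelium and interferon gamma genes were chosen after values of some of their members had been seen. The tests of macrophage number, peritoneal macrophages, dilution and fat tissue were also chosen after the result was seen, the test of fat tissue on genes whose values had not been seen, in place of an earlier test on members of the adipocyte list that restated the result. The tests with the tubule covariate were set before its result was seen, with a bound of 50% of the median without it, but how far the spread should clear that bound was chosen after the values were seen and changed more than once.

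Genes of hepatocytes lay highest on the array of intrakidney tumor 3, and less so on that of intrakidney tumor 2. Albumin (Alb) measured 5.88, 7.20 and 11.83 in intrakidney tumors 1, 2 and 3 and 5.50 to 5.60 in the subcutaneous tumors (limma, adjusted p = 0.654). The mean over 25 hepatocyte genes lay at -0.12, 0.25 and 2.37 relative to the subcutaneous mean, against -0.09 to 0.13 for the subcutaneous tumors, with 0 genes past the threshold over all genes and 0 adjusted over the list alone. The list passed with camera (median 0.72, adjusted p = 2.08e-06; adjusted p = 0.405 with an estimated correlation), and the 8 members not seen when it was written had a median of 0.44 (adjusted p = 0.0156; adjusted p = 0.592 with an estimated correlation). The median was -0.30 with the tubule covariate (adjusted p = 2.358e-05) and -0.105 without intrakidney tumors 2 and 3 (adjusted p = 0.120). Genes of the acute phase, liver and inflammatory proteins, lay at 0.66, 0.45 and 2.01 (median 1.04, adjusted p = 2.627e-09; adjusted p = 0.256 with an estimated correlation), with Lrg1 past the threshold, 6 of 13 members higher when adjusted over the list alone, haptoglobin (Hp) at 2.43 and Saa3 at 2.13. Its 3 unseen members had a median of 0.17 (adjusted p = 0.643), and the list's median was 0.09 with the tubule covariate and 0.47 without intrakidney tumors 2 and 3 (adjusted p = 0.00413 and 1.631e-06).

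Genes of mesothelium, the lining of body cavities, had a median of 0.21 (adjusted p = 0.000359; adjusted p = 0.256 with an estimated correlation), with 3 members higher adjusted over the list alone and 0 past the threshold over all genes, and Upk1b at 0.79 (adjusted p = 0.0533). Their 9 unseen members had a median of 0.18 (adjusted p = 0.0144; adjusted p = 0.592 with an estimated correlation). The list no longer passed with the tubule covariate (median 0.06, adjusted p = 0.217) or without intrakidney tumors 2 and 3 (0.01, adjusted p = 0.287). Interferon gamma-induced genes had a median of -0.17 (adjusted p = 0.0983, or 0.594 with an estimated correlation). Relative to the subcutaneous mean they lay at 0.27, -0.26 and -0.44 in intrakidney tumors 1, 2 and 3. Subcutaneous tumors 1, 2 and 3 lay at 0.25, -0.13 and -0.12. The list's median was 0.17 with the tubule covariate (adjusted p = 0.00413 with camera's preset correlation). Without intrakidney tumors 2 and 3 it was 0.22, where the 1 intrakidney tumor left lay near subcutaneous tumor 1. Other lists hold 1 hepatocyte, 2 acute phase, 2 mesothelium, 2 peritoneal macrophage and 7 interferon gamma genes. Among the genes past the threshold, chosen here after their values were seen, Cd207, which encodes langerin of epidermal Langerhans cells, fell by 0.63 ± 0.08 on the log2 scale (SE, adjusted p = 0.0299), and Sprr1b, a cornified envelope gene, fell by 0.80 ± 0.10 (adjusted p = 0.0416). Fcna, a ficolin of macrophages, rose by 0.76 ± 0.07 (adjusted p = 0.0117).

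Matrix genes were lower in intrakidney tumors with camera's preset correlation, but did not pass with an estimated correlation (adjusted p = 0.285). With the tubule level as a covariate the median was -0.771 (95% bootstrap interval over members -0.878 to -0.238, against -0.547 without it). It lay between -0.924 and -0.610 when each array was left out. This argues against the tissue that proximal tubule transcripts follow as the whole cause, and other kidney tissue was not tested as a cause. The cell cycle median exceeded the matrix median by 0.554 (0.161 to 0.838) and by 0.861 with the covariate (0.328 to 1.009). Without intrakidney tumors 2 and 3, where 1 intrakidney array remained, it did so by 0.737 (0.395 to 0.992). These intervals are over genes that vary together and leave out variation between mice. Relative to the subcutaneous mean, matrix genes lay at -0.566, -0.678 and -0.168 in intrakidney tumors 1, 2 and 3. Cell cycle genes lay at 0.123, 0.025 and -0.082. This argues against dilution of the whole sample in tumors 1 and 2 and leaves it open in tumor 3. A difference in the fibroblasts of the injection site, which the design names, stays open and was not tested.

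Genes of alternatively activated macrophages were higher with camera's preset correlation, but did not pass with an estimated correlation (adjusted p = 0.0850). With the tubule covariate the median was 0.308 (0.038 to 0.536, against 0.292) and between 0.259 and 0.320 when each array was left out. The covariate thus did not lower it. Over members its excess above 50% of the median without the covariate ran from -0.042 to 0.315, on both sides of that bound. The covariate is a mean of proximal tubule genes and was not tested on other kidney tissue. It also moved the median of the hepatocyte list from 0.723 to -0.3, so it does not separate kidney from liver transcripts. A contribution of kidney tissue stays open. Their median exceeded that of general macrophage genes by 0.217 (0.055 to 0.475), but by 0.153 with the covariate (-0.152 to 0.405) and by 0.037 without intrakidney tumors 2 and 3 (-0.191 to 0.333), which leaves more macrophages of every kind open. Macrophages of the peritoneal cavity may contribute: that list passed (median 0.491, adjusted p = 2.287e-12; adjusted p = 0.0166 with an estimated correlation), with Alox15 and Vsig4 past the threshold and 10 of 15 members higher adjusted over the list alone, but 6 members had been seen when it was written. Over the 9 unseen members the median was 0.209 (-0.011 to 0.491, adjusted p = 0.00448; adjusted p = 0.453 with an estimated correlation), which leaves it open beside the site of growth.

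Adipocyte genes were higher with camera's preset correlation but did not pass with an estimated correlation (adjusted p = 0.171), and fat tissue beside the kidney is a candidate explanation that stays open. Over 12 further adipocyte genes the median was 0.055 (-0.008 to 0.084) and camera did not pass, with 8 higher and 0 past the threshold adjusted over these genes alone, which gives fat tissue no support and does not exclude it. With the tubule covariate the list's median was 0.079 (0.009 to 0.656, against 0.153) and between 0.067 and 0.156 when each array was left out, so that it reached 50% of the median without the covariate, 0.077, by less than its spread, and a contribution of kidney tissue stays open. The site of growth, which the design names, stays open too and was not tested.

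The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 46 genes, 26 higher, 20 lower and 18 at least 2-fold, and was the only 1 of the 10 to reach each of these counts, with 0 as the highest of the other splits. It gave 11 lists, a number reached by 4 of the 10 splits, with 13 as the highest of the others.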
